A study of Mus musculus with 24 samples.

How the data were processed

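Gene expression was measured by sequencing polyadenylated RNA in 24 libraries of mouse bone marrow-derived macrophages, the adherent phagocytes grown from marrow precursors. Per the labels' protocols, tibial marrow of 2 to 3 month old C57BL/6 mice was expanded with IL-3 and the macrophage growth factor CSF-1, starved of serum for about 16 hours and left untreated or given TGF-β1 for 4 hours. Per the labels, 4 genotypes were grown with 3 libraries per genotype and treatment: mice with a floxed Smad2 gene (Smad2fl), the same line with LyzM-Cre (MyS2KO), mice with a floxed Smad3 gene (Smad3fl), and that line with LyzM-Cre (MyS3KO). LyzM-Cre drives the recombinase from the lysozyme gene Lyz2 in myeloid cells. Nothing in the labels says whether the 3 libraries of a group come from separate animals, so every p-value here measures only the spread between libraries. The labels' protocols speak of 8 cDNA libraries while 24 samples are deposited, so whether RNA was pooled is not known, and the 3 libraries per group rest on the deposited samples.

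Per the labels' protocols, libraries were made with the NEBNext Ultra RNA kit and read as pairs of 150 bases on a NovaSeq instrument. Per the submitters' processing notes, TopHat2 2.0.9, HTSeq 0.6.1 and Cufflinks 2.1.1 were used with mm10 and GRCm38.p6. The role of each tool, the counting mode and the strand setting are not given in the sources used here. Genes that overlap on opposite strands and close paralogs therefore carry an uncertainty that the counts cannot resolve.

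The authors deposited raw read counts for 54532 Ensembl genes, and 26189 of them had no read in any library. The deposited FPKM values can be computed from the same counts with a length per gene and the total of each library, so they are a second unit and no second measurement. Of the gene symbols, 103 belong to more than 1 Ensembl identifier, and such genes were followed by identifier. Libraries held 16.9 to 24.9 M counted reads (M, 1e6). The 4 Y-linked genes looked at reached 0.26 CPM at most and Xist lay between 115 and 911 CPM in all libraries, the pattern of female cells, so the counts show no mix of sexes. Sequence reads were not analysed here.

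Counts were scaled by TMM factors, genes were kept by the filterByExpr rule of edgeR on the 8 groups, and 14261 genes were tested. Changes were fitted with edgeR 4.0.16 in R 4.3.3, all 24 libraries in 1 model with a mean per group, and tested with the edgeR quasi-likelihood test. P-values were adjusted by Benjamini and Hochberg within each comparison over all tested genes, and a gene was called at an adjusted p under 0.05. The median gene-wise biological coefficient of variation was 21.2%, with 16 residual and 6.1 prior degrees of freedom. Log2 changes are fitted values with the standard error after ±. Levels are CPM, the deposited counts per 1e6 reads of the TMM-scaled library total, given as mean ± SD of 3 libraries. No fold is given where 1 group had no read at all. In its place stands the least fold that remains if that group had held 3 reads in all.

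TGF-β1 was compared with no treatment in each of the 4 genotypes, and knockout with floxed libraries in each line with and without TGF-β1. The interaction of knockout and TGF-β1 was tested in each line. Between lines, the knockout effects under each treatment, the interactions and the TGF-β1 responses of the floxed libraries were compared, and so were the untreated floxed libraries themselves. Interactions are the log2 response of the knockout libraries minus that of the floxed libraries. Lines differ in more than the targeted gene, so only comparisons within a line set knockout libraries against floxed libraries of the same line. The labels do not say whether these floxed and knockout libraries share a culture batch or litter. Differences other than the knockout can therefore enter comparisons within a line as well. A knockout effect is here the difference between knockout and floxed libraries of a line, whatever its cause.

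In all, 32 gene lists, fixed before any value was seen, cover TGF-β targets, SMAD pathway members, macrophage functions, stress responses, metabolism, markers of other cell types and signs of RNA quality. Their 558 symbols were all present in the deposited table. The mast cell and basophil list had fewer than 3 tested members and was not tested. Lists were tested with fry of limma 3.58.1, which asks whether members moved in 1 direction and does not compare them with other genes, and its p-values were adjusted over the lists of a comparison. Camera with a correlation estimated from the residuals gave a competitive second test. For each list the members called over all genes are given first, then those with p adjusted over the list alone.

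A further list test used genes chosen in the other line. Genes called with at least a doubling or halving by TGF-β1 in Smad3fl were followed in the interaction of the Smad2 line, and those of Smad2fl in the interaction of the Smad3 line. The genes are thus chosen in libraries that take no part in the comparison.

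Genes named in the results follow a rule fixed beforehand: the SMAD genes and Lyz2 in the knockout comparisons, the 10 largest called changes each way of every comparison of 2 groups, the 8 largest each way of comparisons of differences, and up to 4 called members per list with the smallest p. The largest changes had to be protein-coding, reach a mean of 1 CPM in the higher group, show no overlap of the groups and carry an established symbol. With 3 libraries a side, groups separate by chance alone in 10% of genes. Not all genes that the rule admits are named, some are not reported here, and members of the TGF-β feedback, phagocytosis and matrix lists may be given whether called or not.

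Other settings tried were RLE scaling, no low-count filter (28343 genes), DESeq2 1.42.0, limma on the log2 of the deposited FPKM plus 1 (12214 genes), and the groups of a comparison on their own. A block for the number 1 to 3 of a library within each line was fitted, and each library was left out in turn. A block for that number within each genotype, and runs without both libraries of a number in Smad3fl or without both MyS3KO libraries numbered 1, were added after the values were seen, as was an offset for gene length. In counts simulated from these libraries with 200 changed genes, edgeR recovered 50% of doublings and 69% of 4-fold changes in a comparison of 2 groups. For an interaction it recovered 18% and 55%, so interactions of moderate size are mostly missed. Of the edgeR calls 1.7% and 5.2% were false, of the DESeq2 calls 10.4% and 17.2% and of the limma calls 1.9% and 8.1%. The simulated counts were drawn independently around a common mean per gene. They lack the differences between lines and the resemblance between libraries that the data hold, so these shares may be too favourable for the data.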

Results

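The data are 24 libraries of bone marrow-derived macrophages from 4 genotypes, untreated or treated with TGF-β1 for 4 hours, 3 libraries per group. Mean depth (M, 1e6 counted reads) was 22.4 M in untreated Smad2fl (24.9, 21.2 and 21 M), 21.1 in treated Smad2fl (20.9, 22.8, 19.5), 20.5 in untreated MyS2KO (17.2, 22.9, 21.3) and 20 in treated MyS2KO (17.7, 20.4, 22.1). In the Smad3 line it was 22.5 in untreated Smad3fl (22.4, 21.7, 23.3), 18.8 in treated Smad3fl (19, 20.6, 16.9), 19.5 in untreated MyS3KO (18.4, 19.5, 20.4) and 19.4 in treated MyS3KO (18.2, 18.4, 21.5). Mitochondrial transcripts made up 0.65% to 0.96% of reads by group. Transcripts of ribosomal proteins made up 1.13±0.27% and 1.06±0.09% of reads in untreated and treated Smad3fl against 1.75±0.11% to 2.03±0.18% in the other 6 groups.

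Smad2 (ENSMUSG00000024563, chr18:76241580-76305731, mm10), the receptor-activated SMAD targeted in the first line, was at 42.2±3 CPM in untreated and 37.7±1.6 in treated Smad2fl, and at 40.4±2.9 and 40.3±6.3 CPM in MyS2KO. The change was -0.06±0.12 without TGF-β1 (adjusted p = 0.924) and 0.09±0.12 with it (adjusted p = 0.891), and single libraries of all groups lay between 32.3 and 48.4 CPM. Gene-level Smad2 RNA was thus not lower in the knockout, against its label, and the group is called the libraries labelled MyS2KO. The submitters' design text says that the loss was documented by qPCR and western blot, measurements not used here, and a count over the whole gene does not resolve deleted exons. An exchange of labels within this line was not tested and is not excluded by the Smad2 counts. Lyz2, which carries the recombinase, was lower in the libraries labelled MyS2KO under both treatments (-0.89 and -0.96, neither called). The directions of this line still rest on the labels. Smad3 (ENSMUSG00000032402, chr9:63646767-63757994), the receptor-activated SMAD targeted in the second line, fell from 424±48 to 184±24 CPM untreated (-1.21±0.14, adjusted p = 6.91e-06) and from 415±23 to 268±20 with TGF-β1 (-0.63±0.13, adjusted p = 0.00208). Its single values were 443, 460 and 369 CPM in untreated and 404, 442 and 400 in treated Smad3fl, against 209, 181 and 161, and 289, 250 and 265, in MyS3KO. The MyS3KO libraries still held several times the Smad3 level of the Smad2 line, which was 41.5±4 CPM in untreated and 57.2±8.4 in treated Smad2fl and 31.3±4.2 and 49.4±3.1 in MyS2KO. Gene-level Smad3 RNA was thus lowered and not lost, and as for Smad2 the count does not resolve deleted exons. Smad3 loss below is only the name of the comparison of MyS3KO with Smad3fl. Smad4 (chr18:73639009-73703780), the shared partner of both, lay between 44.5 and 50.3 CPM in all groups. Lyz2 (ENSMUSG00000069516, chr10:117277331-117282321), the lysozyme gene that carries the recombinase, was at 11200±400 CPM in untreated Smad2fl and 6070±760 in MyS2KO (-0.89±0.37, adjusted p = 0.502), and at 4050±2400 in untreated Smad3fl and 2890±1300 in MyS3KO (-0.48, adjusted p = 0.394). With TGF-β1 its changes were -0.96±0.37 (adjusted p = 0.367) and -0.06 (adjusted p = 0.922).

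**Figure D1:**
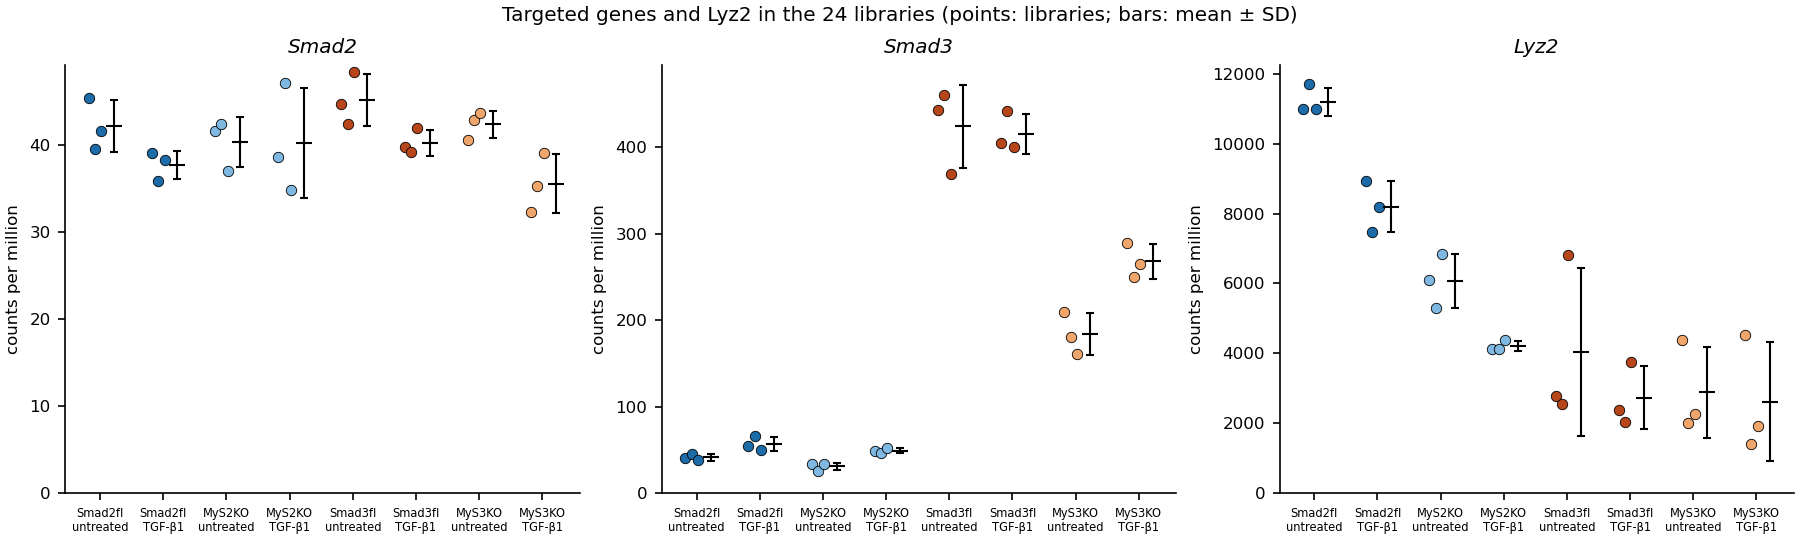
Levels of Smad2, Smad3 and Lyz2 in CPM in the 8 groups, points for libraries and bars for mean and SD. Smad2 is level in all groups, and Smad3 is high in Smad3fl and lower but still present in MyS3KO.

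Most Smad3fl libraries lay apart from the other groups. On the first principal component of all tested genes (32.7% of variance) Smad3fl libraries numbered 1 and 2 scored 63.8 and 68.7 untreated and number 3 scored 6.9, close to MyS3KO, while treated Smad3fl libraries scored 66.5 to 83.1. The second component (15.8%) parted treated from untreated libraries within each genotype. The interferon-inducible gene Ifi202b was at 80.7 to 275 CPM in Smad3fl, at 68.9 to 104 in MyS3KO libraries numbered 2 and 3, at no more than 1.25 in those numbered 1, and at no more than 0.46 in the Smad2 line. The antiviral gene Trim12a (chr7:104299894-104315466) was nearly absent from Smad3fl libraries numbered 3 (0.42 and 0.84 CPM) and from MyS3KO. Nlrp1a, an inflammasome sensor, was at 12.9 and 9.01 CPM in Smad3fl libraries numbered 3 and at 0 in numbers 1 and 2.

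**Figure D2:**
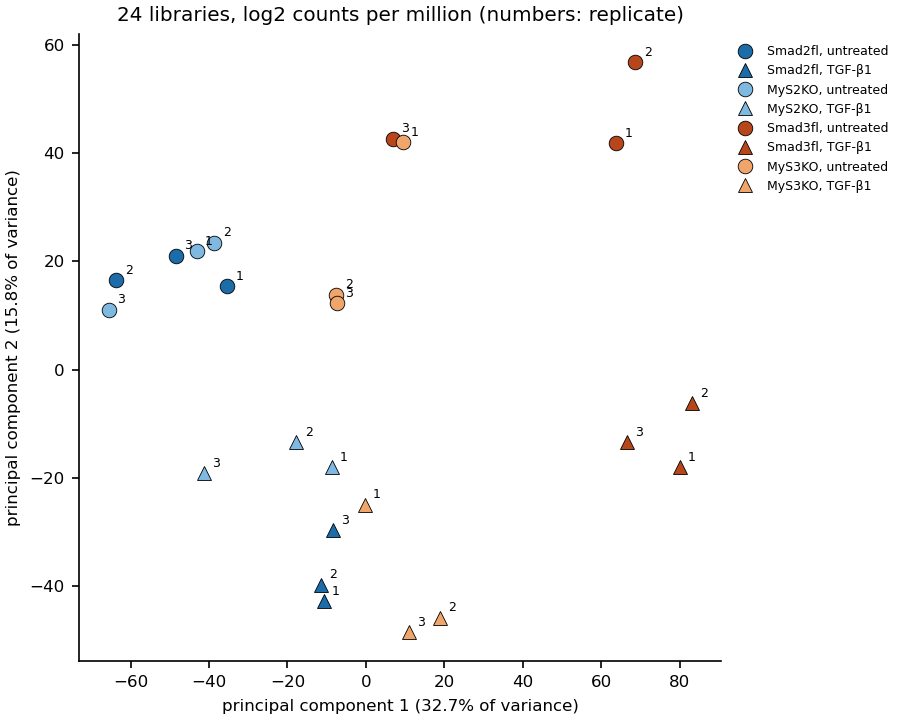
First and second principal component of log2 levels for the 24 libraries, circles untreated, triangles TGF-β1, numbers for replicate. All Smad3fl libraries but untreated number 3 lie far from the rest on the first component, and treatment separates within genotypes on the second.

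TGF-β1 raised a shared set of its own feedback inhibitors in every genotype. Pmepa1 (ENSMUSG00000038400, chr2:173224458-173276533), which sequesters receptor-activated SMADs, rose in Smad2fl from 0.0571 to 28.1±2.9 CPM (8.67±0.49, adjusted p = 3.19e-11) and in the libraries labelled MyS2KO from 0.148 to 11.1±4.1 (6.26±0.45, adjusted p = 2.95e-09). It rose in Smad3fl from 0.044 to 33.8±9.3 (adjusted p = 3.24e-11) and in MyS3KO from 0.0199 to 28.6±2.7 (adjusted p = 2.83e-11), untreated levels that rest on 3 reads and 1 read over the group. Smad7 (ENSMUSG00000025880, chr18:75367529-75395935), the inhibitory SMAD, rose by 5.32±0.23, 4.47±0.22, 6.25±0.24 and 5.71±0.23 in the same order, to 42.4±1.6, 24.1±1.4, 52.3±4.7 and 42.6±4.1 CPM. Tgfbi (chr13:56609523-56639562), a secreted matrix protein named for its induction by TGF-β, rose by 3.81±0.24, 3.29±0.24, 4.4±0.25 and 4.59±0.25 and was the most abundant of these genes, at 730±85 CPM in treated Smad2fl and 451±63 in MyS2KO. Smad6, which blocks BMP receptors, rose by 4.54±0.28, 4.54±0.29, 4.69±0.29 and 5.9±0.31, and the corepressor Ski by 2.12, 1.70, 1.69 and 1.76.

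In Smad2fl 1584 genes were called, 1051 higher and 533 lower, with 570 at least doubled and 161 at least halved. Cx3cr1 (chr9:119901616-120069879), the fractalkine receptor of resident macrophages and microglia, rose from 0.0353 to 4.52±1.3 CPM (2 to 288 reads over the group, adjusted p = 3.42e-07), the exchange factor Spata13 from 0.887 to 40.7 CPM (5.5±0.31), and Znrf3, which removes Wnt receptors, by 5.41±0.53. The scavenger receptor gene Olr1 went from 3 to 185 reads over the group and the thrombin receptor gene F2r from 3 to 158. Tmeff1 (chr4:48585174-48663131), a membrane protein that binds activin coreceptors, went from no read to a level at least 66.4-fold higher. The proteoglycan Cspg4 went from no read to at least 38.4-fold. Falls were led by Rasgrp1 (-2.96±0.71), a Ras activator, the apelin receptor Aplnr (-2.78), the dendritic cell repressor Zfp366 (-2.71), the orphan receptor Gprc5c (-2.5±0.46, 9.18 to 1.61 CPM), Tubb3 (-2.24±0.35) and Asb2 (-2.24). Cebpd (chr16:15887286-15891031), a factor that amplifies inflammatory transcription, fell from 173±51 to 35.4±1 CPM (-2.29±0.30, adjusted p = 9.17e-06). Leaving out untreated Smad2fl library 2 gave the lowest count of any run without 1 library, 1057.

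In the libraries labelled MyS2KO 486 genes were called, 414 higher and 72 lower, 237 at least doubled and 12 at least halved. Tmeff1 went from 3 to 79 reads over the group, Spata13 rose by 4.69±0.31, the deubiquitinase Usp2 by 4.5±0.39, the secreted Angptl2 by 4.05±0.32 and Cx3cr1 by 3.55±0.53 (adjusted p = 0.00014). Ermap, an erythroid surface protein, went from no read to at least 47-fold. The falls were fewer and smaller. Cdkn2b, an inhibitor of the G1 kinases, fell by 1.54±0.25 (9.45 to 3.25 CPM), Tubb3 by 1.34±0.33 and the deubiquitinase Otub2 by 1.3±0.29. Sik1 fell by 1.21±0.28, Cebpd by 1.08±0.29 (adjusted p = 0.0369, 197 to 92.8 CPM), Myc by 1.08±0.28 and the actin regulator Rnd3 by 1.07±0.19. Without treated MyS2KO library 1 the count was 316, and with a block for the library number within each genotype 1032. The r of libraries of equal number was 0.15, 0.22 and 0.41 (highest other 0.2), and the block raised the count in all genotypes.

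In Smad3fl 1714 genes were called, 910 higher and 804 lower, 523 at least doubled and 238 at least halved. Which direction prevails was not stable: 898 higher and 1095 lower without untreated library 1, 781 and 872 without untreated library 2, and 1564 and 1742 with a block for the library number within each genotype. The serine protease gene Prss46 went from 1 to 77 reads over the group. Tmeff1 rose by 4.83±0.58, the endothelial phosphatase Pald1 by 4.71±0.48, Spata13 by 4.33±0.27 and Cx3cr1 from 0.945 to 16.8±4.1 CPM (4.13±0.45). The salt-inducible kinase Sik1 fell by 2.54±0.36, the iron exporter Slc40a1 from 86.5±41 to 16.2±4.4 CPM (-2.41±0.29), Rasgrp1 by 2.47±0.64, Asb2 by 2.3±0.55, the Wnt receptor Fzd1 by 2.23 and Rnd3 from 43.5 to 10.6 CPM (-2.03±0.20). Libraries of equal number resembled each other here (r = 0.45, 0.34 and 0.33, highest other -0.09), and that block raised the count to 3306. Without treated Smad3fl library 1 it was 1136. Without both Smad3fl libraries numbered 3 it was 978, against 1130 and 1138 without numbers 1 and 2.

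In MyS3KO 1428 genes were called, 933 higher and 495 lower, 506 at least doubled and 211 at least halved. Without a low-count filter falls prevailed, with 818 higher and 898 lower. Ermap went from 3 to 444 reads over the group, Cspg4 from 1 to 94 and the Notch target Hey1 from 1 to 59. Tmeff1 rose by 5.8±0.63, Spsb1, an adaptor that marks TGF-β receptors for degradation, by 4.89±0.44, and Pald1 by 4.75±0.50. Il6, the inflammatory cytokine, fell by 3.39±0.93 (adjusted p = 0.0198), Sik1 by 2.74±0.39, Casp12 by 2.49±0.66, Fzd1 by 2.43, Slc40a1 from 47.8 to 10.8 CPM (-2.15±0.29) and Tnfsf15 from 39.2 to 9.09 CPM (-2.12±0.40). Without treated MyS3KO library 3 the count was 914.

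Many calls were shared between genotypes. Of genes raised in the floxed lines 695 were raised in both, against 67.1 were the lists independent, and 404 were lowered in both (30 if independent). Of the 414 genes raised in the libraries labelled MyS2KO 391 were raised in Smad2fl (30.5) and 382 in MyS3KO (27.1), and MyS3KO shared 605 raised (59.5) and 313 lowered genes (27.9) with Smad3fl. Seen from Smad2fl, only 391 of 1051 raised and 66 of 533 lowered genes were called the same way in MyS2KO. Seen from MyS3KO, 382 of 933 raised genes were.

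TGF-β feedback genes and SMAD targets (25 tested) had 15 higher and 2 lower in Smad2fl, 15 and 2 in the libraries labelled MyS2KO, 15 and 4 in Smad3fl and 16 and 2 in MyS3KO. There were 17 and 2, 16 and 3, 16 and 6, and 17 and 2 adjusted over the list alone. Median changes were 1.22, 1.05, 0.91 and 1.06 (fry adjusted p = 3.18e-11, 4.82e-10, 2.27e-10 and 1.98e-11), and all held with an estimated correlation (largest adjusted p = 2.05e-05). ID genes and targets of BMP-activated SMADs (6 tested) rose with medians of 2.43, 2.68, 1.12 and 3.34, with 5, 5, 3 and 5 called and 6, 5, 5 and 5 adjusted over the list alone (largest fry adjusted p = 7.16e-09, with an estimated correlation 0.000276). Id2, which holds back differentiation, rose by 1.83±0.24, 1.41, 1.08 and 1.89, and Id3, its paralog, by 2.58±0.34, 2.37 and 3.88±0.37 in Smad2fl, MyS2KO and MyS3KO, with no call in Smad3fl. Among SMAD pathway members (17 tested) 5, 4, 5 and 5 were higher, 5 in each adjusted over the list alone, with medians of 0.25, 0.27, 0.11 and 0.10 (largest fry adjusted p = 4.82e-10, with an estimated correlation 0.000232). The type I receptor Tgfbr1 led them (2.74±0.29, 2.29, 2.34 and 2.04).

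Microglia genes that depend on TGF-β (9 tested) had 4, 4, 5 and 4 higher, and 4, 4, 5 and 5 adjusted over the list alone besides 1 lower in Smad3fl. Fry gave adjusted p = 4.75e-07, 6.63e-05, 1.16e-07 and 3e-07, and the calls held with an estimated correlation (0.00682, 0.00963, 0.0014 and 0.0028). Medians were 0.5, -0.09, 0.89 and 0.94, the MyS2KO median being negative while its mean was 0.77 and fry was up. Olfml3, a secreted microglial protein, rose by 2.81±0.32, 2.13, 3.6 and 4.10 and the receptor Gpr84 by 1.97, 1.83, 1.83 and 2.28. Growth factors (17 tested) had 5 higher and 1 lower, 4 and 0, 5 and 2, and 4 and 2, and 6 and 2, 4 and 1, 5 and 2, and 4 and 2 adjusted over the list alone (medians 0.54, 0.15, 0.32 and 0.39; largest fry adjusted p = 2.77e-06). In Smad3fl that call was lost, at adjusted p = 0.0547 with an estimated correlation. Pdgfa, a mitogen of mesenchymal cells, rose by 3.97±0.33, 2.91, 3.33 and 4.01, Pdgfb by 2.88, 2.24, 3.02 and 3.52, oncostatin M (Osm) by 2.68, 1.53, 2.55 and 2.49, and the vessel growth factor Vegfa by 1.44, 1.01, 0.80 and 1.41.

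Chemokine receptors and migration genes (16 tested) had 5 higher and 2 lower, 4 and 0, 4 and 2, and 4 and 2, and 6 and 2, 4 and 2, 5 and 2, and 4 and 2 adjusted over the list alone (largest fry adjusted p = 3.72e-05; in Smad3fl adjusted p = 0.0788 with an estimated correlation). Cxcr4, the receptor that retains cells in marrow, rose by 3.10±0.18, 2.50, 2.22 and 3.03 and the sphingosine receptor S1pr1 by 2.81±0.22, 2.61, 1.71 and 2.05, while the formyl peptide receptor Fpr1 fell by 0.93 in Smad2fl and 1.13 in Smad3fl. Integrins and adhesion genes (17 tested) had 4 higher and 1 lower, 4 and 0, 4 and 2, and 5 and 1, and 5 and 1, 4 and 0, 5 and 5, and 5 and 1 adjusted over the list alone. Medians were -0.16, -0.01, -0.19 and 0.01 while means were positive (0.27, 0.21 and 0.06 in the first 3 genotypes) and fry was up (adjusted p = 0.000545, 0.00156, 0.105 and 0.000217). The calls were lost at adjusted p = 0.378, 0.156 and 0.169 with an estimated correlation. Itgav, Itgb5 and Itga5, subunits of fibronectin and vitronectin receptors, rose by 1.95±0.19, 1.43, 1.33 and 1.67, by 1.81, 1.37, 1.85 and 2.04, and by 1.2, 0.77, 0.91 and 1.54.

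Matrix genes (15 tested) had 2 higher and 0 lower, 1 and 0, 3 and 1, and 1 and 1, and 2 and 0, 1 and 0, 3 and 2, and 1 and 1 adjusted over the list alone. Fibronectin (Fn1) rose in Smad3fl by 1.87±0.38, and tenascin C (Tnc), a matrix protein of injured tissue, went from 3 to 24 reads there and rose by 2.62±0.81 in Smad2fl. Medians were -0.06, 0.02, 0.24 and 0.15 (fry up, adjusted p = 0.0153, 0.0444, 0.00133 and 0.0296), the Smad2fl median and mean (-0.03) having the other sign, and all were lost at adjusted p = 0.573, 0.525, 0.214 and 0.67 with an estimated correlation. Matrix proteases and inhibitors (19 tested) had 6 higher and 1 lower, 1 and 0, 5 and 1, and 5 and 1, and 6 and 1, 1 and 0, 6 and 1, and 5 and 1 adjusted over the list alone. The protease gene Adamts4 fell by 1.4, 1.53 and 1.21 in Smad2fl, Smad3fl and MyS3KO. Fry gave adjusted p = 0.0285, 0.162, 0.0585 and 0.0378, lost at adjusted p = 0.573 and 0.67 with an estimated correlation.

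Macrophage identity genes (15 tested) had no common direction (fry adjusted p = 0.853, 0.663, 0.839 and 0.403), yet the myeloid factor Cebpa rose by 2.79±0.29, 2.47, 2.80 and 2.92. Lipid efflux genes (12 tested; 3, 3, 2 and 2 higher) included the cholesterol exporters Abca1 (1.74±0.21, 1.55, 1.55 and 1.37) and Abcg1 (1.12, 0.88, 1.22 and 1.09). Fry was up (adjusted p = 0.0153, 0.00844, 0.0497 and 0.0013) with medians of -0.03 and -0.06 in Smad2fl and Smad3fl, and the calls were lost at adjusted p = 0.573, 0.174, 0.609 and 0.184 with an estimated correlation. Alternative activation genes (17 tested) had 1 higher and 3 lower, 1 and 1, 1 and 3, and 2 and 3, and 2 and 6, 1 and 2, 1 and 4, and 4 and 3 adjusted over the list alone. They were down in Smad2fl and Smad3fl (fry adjusted p = 0.03, 0.464, 0.044 and 0.342 over the genotypes), both lost at adjusted p = 0.378 and 0.606 with an estimated correlation. Their lipid-sensing factor Pparg fell by 1.51±0.18, 1.01, 1.67 and 1.38. Inflammatory cytokines (24 tested; 0 higher, and 2, 1, 5 and 2 lower, with 2, 1, 6 and 2 adjusted over the list alone) passed in no genotype (fry adjusted p = 0.345, 0.542, 0.0768 and 0.197). Nfkbiz, a coactivator of NF-κB, fell by 0.96±0.11, 0.71, 0.94 and 0.83, and Il1b by 1.87 and Cxcl1 by 1.74 in Smad3fl.

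Immediate early genes (19 tested) did not pass (fry adjusted p = 0.768, 0.464, 0.465 and 0.206), though the AP-1 gene Fos rose by 1.86±0.20, 1.45, 1.78 and 2.06. Cell cycle genes (27 tested; 3, 2, 3 and 5 higher, 3, 2, 3 and 6 adjusted over the list alone) were up by fry in Smad2fl, Smad3fl and MyS3KO (adjusted p = 0.00258, 3.72e-05 and 8.9e-06) and not in the libraries labelled MyS2KO (0.129). With an estimated correlation adjusted p = 0.573, 0.0788 and 0.0417, so only MyS3KO kept the call. The replication genes Cdt1 and Mcm6 rose by 1.23, 1.2, 0.85 and 1.62 and by 0.95, 0.56, 1.28 and 1.35. Glycolysis genes (23 tested; 4, 2, 2 and 4 higher) had fry adjusted p = 0.371, 0.037, 0.227 and 0.00155, lost at adjusted p = 0.571 and 0.382 with an estimated correlation, and hexokinase 2 (Hk2) rose by 1.29±0.12, 0.97, 0.46 and 1.03. The oxidative stress list (13 tested; fry adjusted p = 0.0821, 0.542, 0.839 and 0.56) included the glutathione synthesis subunit Gclm (2.18, 1.34, 1.63 and 1.6). The stress and unfolded protein list (17 tested) had fry adjusted p = 0.173, 0.542, 0.0421 and 0.504, down in Smad3fl with 4 called lower and 10 adjusted over the list alone, and lost at adjusted p = 0.609 with an estimated correlation.

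Phagocytosis genes (30 tested; 4, 4, 4 and 5 higher and 1, 0, 1 and 0 lower) had no direction (fry adjusted p = 0.917, 0.542, 0.87 and 0.184), with the efferocytic receptor Lrp1 up by 0.51, 0.57 and 0.58 in Smad2fl, MyS2KO and MyS3KO. Other lists gave no call by fry in any genotype: type I interferon response (lowest adjusted p = 0.198), antigen presentation (0.0507), cholesterol synthesis (0.117) and lysosome (0.414). Osteoclast genes had none either (0.28). Of markers of other cells, neutrophil (0.542), dendritic (0.115) and erythroid genes (0.0561) did not pass. Stromal genes passed in the libraries labelled MyS2KO (fry adjusted p = 0.0444; adjusted p = 0.525 with an estimated correlation), where the bone regulator Runx2 rose as in every genotype (2.19, 1.35, 1.58 and 1.14). The 3 lymphocyte genes were up in Smad3fl (median 0.92, fry adjusted p = 0.0027) and down in MyS3KO (-0.47, 0.00465), both lost at adjusted p = 0.613 and 0.678 with an estimated correlation. Neither mitochondrial transcripts (0.129) nor heat shock genes (0.0502) passed, though the chaperone partner Bag3 rose by 1.00, 0.80, 1.15 and 1.29.

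**Figure D3:**
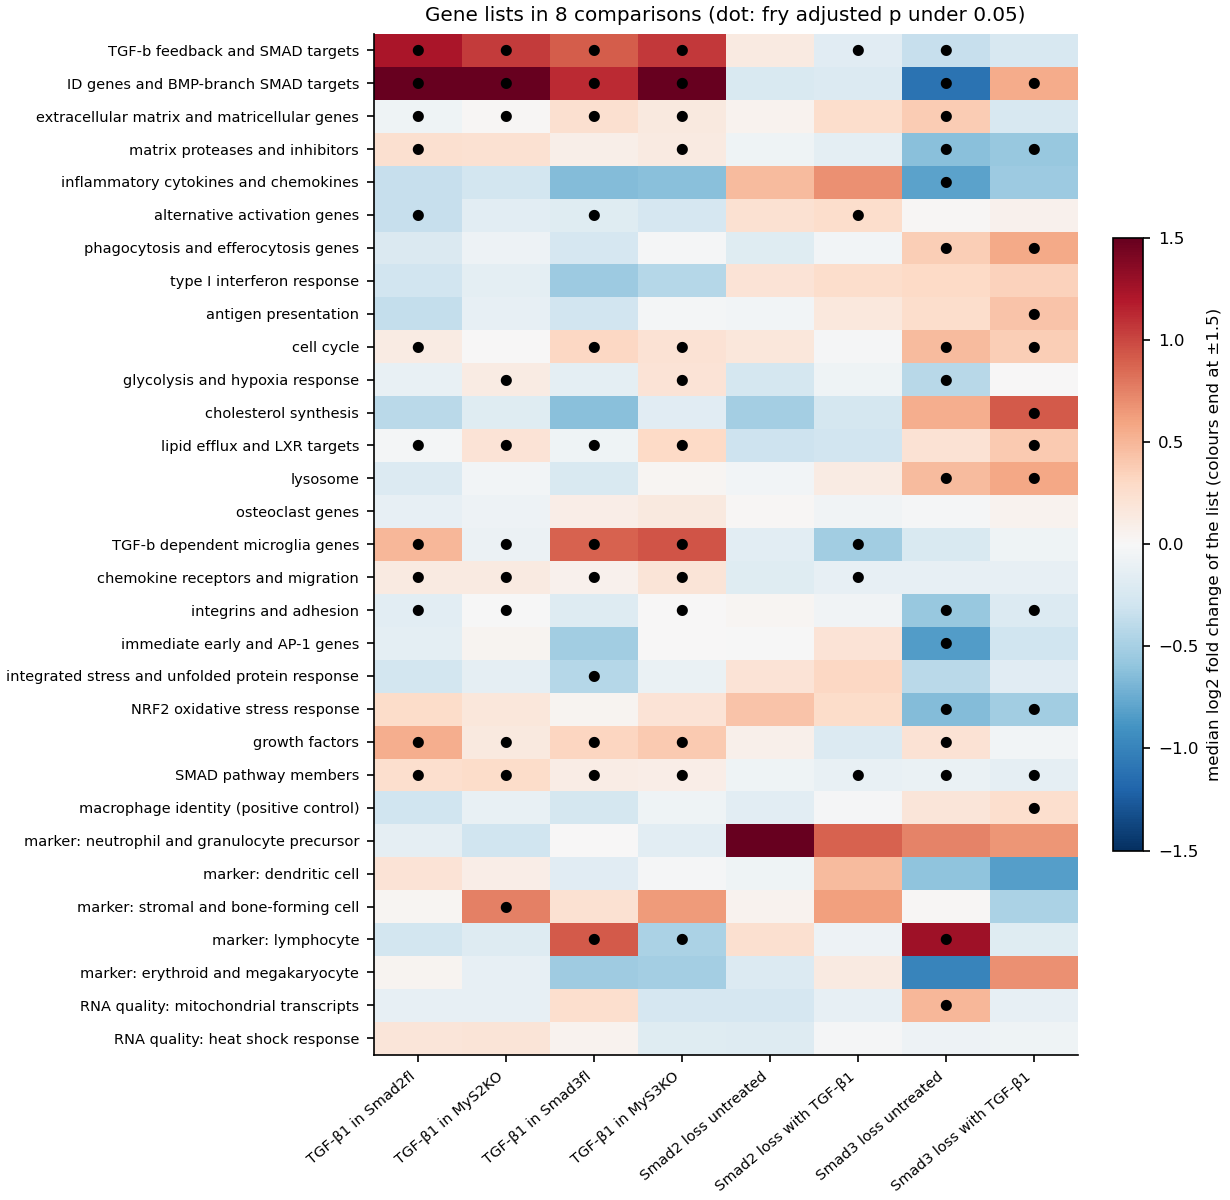
Median log2 change of 31 gene lists in 8 comparisons, colours ending at 1.5 either way, a dot where the fry adjusted p is under 0.05. TGF-β feedback and ID lists are raised by TGF-β1 in all genotypes, and many lists differ between MyS3KO and Smad3fl, calls that were lost with an estimated correlation.

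Between the untreated libraries of the Smad2 line 10 genes were called, 5 each way, and 1254 had an unadjusted p under 0.05. The catalytic subunit of glutathione synthesis, Gclc (chr9:77754535-77794485), was higher in the libraries labelled MyS2KO (8.54±3.2 to 24.9±6.1 CPM, 1.54±0.28, adjusted p = 0.0337), as were the chondroitin sulfotransferase Chst3 (chr10:60181532-60219260; 1.64 to 4.1 CPM, 1.31±0.20, adjusted p = 0.00556), the BCL6 corepressor Bcor (chrX:12036740-12160355; 13.4 to 27 CPM, 1.02±0.14, adjusted p = 0.0034) and Irf2bp2 (37 to 62 CPM, 0.75±0.14, adjusted p = 0.0337). Serpina1e (chr12:103946931-103958975), a secreted liver protease inhibitor, went from no read to at least 23.4-fold. The integrin Itgal (chr7:127296260-127335138) of the LFA-1 receptor fell from 212±21 to 112±7.2 CPM (-0.92±0.14, adjusted p = 0.00556), Etv5 from 119 to 67 (-0.83±0.14, adjusted p = 0.0193). Arhgdib fell from 593 to 347 (-0.77±0.14, adjusted p = 0.0297) and Gna15 from 24.9 to 15 (-0.73±0.14, adjusted p = 0.0337). No list passed (lowest fry adjusted p = 0.155). Counts were 5 without untreated Smad2fl library 2, and 6, 2 and 4 without untreated MyS2KO libraries 1, 2 and 3. They were 101 by DESeq2, 161 without a low-count filter and 0 by edgeR with only the groups compared.

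With TGF-β1 60 genes were called in the Smad2 line, 27 higher and 33 lower, with 15 at least doubled, 8 at least halved and 1313 at an unadjusted p under 0.05. Rises prevailed without a low-count filter (204 and 109) and with a block for the library number within the line (40 and 30). The feedback inhibitor Pmepa1 was lower in the libraries labelled MyS2KO (-1.35±0.28, adjusted p = 0.034), as were Smad7 (-0.81±0.17, adjusted p = 0.0394), Ski (-0.63±0.11, adjusted p = 0.0165), Hk2 (-0.76±0.12, adjusted p = 0.00963), Cxcr4 (-0.86±0.16) and the mitotic scaffold Iqgap3 (-1.04±0.16, adjusted p = 0.00859). Others lower were the actin oxidase Mical2 (28.8 to 13.3 CPM, -1.11±0.21), Fhad1 (76.3 to 35.5, -1.11±0.20), the kinase Nuak1 (-1.09), the glucocorticoid target Fkbp5 (-0.95±0.17) and Enpp1 (-0.89). Cebpd was higher (35.4 to 92.8 CPM, 1.39±0.29, adjusted p = 0.0394), as were Pparg (0.99±0.18, adjusted p = 0.0179), the GTPase genes Gbp8 (3.28±0.62, adjusted p = 0.0179) and Rnd1 (2.15). So were the plasma protein genes Serpina3k (2.5), Hpx (1.94±0.32, adjusted p = 0.00968), Gc (1.6) and Alb (chr5:90460897-90476602; 16.5 to 39.4±9.1 CPM, 1.26±0.27). The TGF-β feedback list was down (median -0.17, fry adjusted p = 0.0135) with 0 higher and 3 lower, and 2 and 8 adjusted over the list alone, and lost at adjusted p = 0.0598 with an estimated correlation. Counts were 0 and 6 without treated Smad2fl libraries 1 and 2, and 37, 0 and 0 without treated MyS2KO libraries 1, 2 and 3. DESeq2 called 214 genes.

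Of other lists in that comparison, the microglia genes were down (median -0.52, 0 called, 4 lower adjusted over the list alone, fry adjusted p = 0.00279) and stayed so with an estimated correlation (adjusted p = 0.0125). SMAD pathway members (median -0.11, 1 lower, 3 adjusted over the list alone, fry adjusted p = 0.0108) and chemokine receptors (median -0.12, 1 lower, 1 adjusted over the list alone, fry adjusted p = 0.0263) were down and lost at adjusted p = 0.0941 and 0.138 with an estimated correlation. Alternative activation genes were up (median 0.26, 1 higher, 2 adjusted over the list alone, fry adjusted p = 0.0174; adjusted p = 0.0598 with an estimated correlation).

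The TGF-β1 response was weaker in the libraries labelled MyS2KO as a whole. The 523 genes at least doubled in Smad3fl had a median response of 1.47 in Smad2fl and 1.02 in MyS2KO, weaker for 90.1% of them, with a median interaction of -0.45 (fry adjusted p = 0.000884). The 238 genes at least halved there had -1.02 and -0.52, weaker for 95%, interaction 0.48 (fry adjusted p = 0.00199), and camera with an estimated correlation gave the same directions. The latter was 0.4 (fry adjusted p = 0.0528) without untreated Smad3fl library 1. In the Smad3 line the 570 genes at least doubled in Smad2fl had a median response of 1.30 in Smad3fl and 1.33 in MyS3KO, weaker for 49.1% (interaction 0.01, fry adjusted p = 0.934). The 161 at least halved had -1.35 and -1.13, weaker for 72% (0.26, fry adjusted p = 0.0927), and without a fold minimum 82.4% of 533 lowered genes were weaker (0.25, fry adjusted p = 0.0431). By single gene only Chst3 was called in the interaction of the Smad2 line (-1.89±0.27, adjusted p = 0.00676), rising from 1.64±0.52 to 18.4±0.73 CPM in Smad2fl and from 4.1±0.8 to 12.3±1.4 in MyS2KO, against 489 genes at an unadjusted p under 0.05 and 5 calls by DESeq2. With an offset for gene length Chst3 was at -1.84±0.31 and, its spread being larger, no longer called (adjusted p = 0.0769; 0 calls by edgeR, 500 genes at an unadjusted p under 0.05). Without untreated MyS2KO library 3 or treated MyS2KO library 2 no gene was called. The count was also 0 with the planned block for the library number within each line, by limma on FPKM and with only the groups compared. No list passed (lowest fry adjusted p = 0.194).

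**Figure D4:**
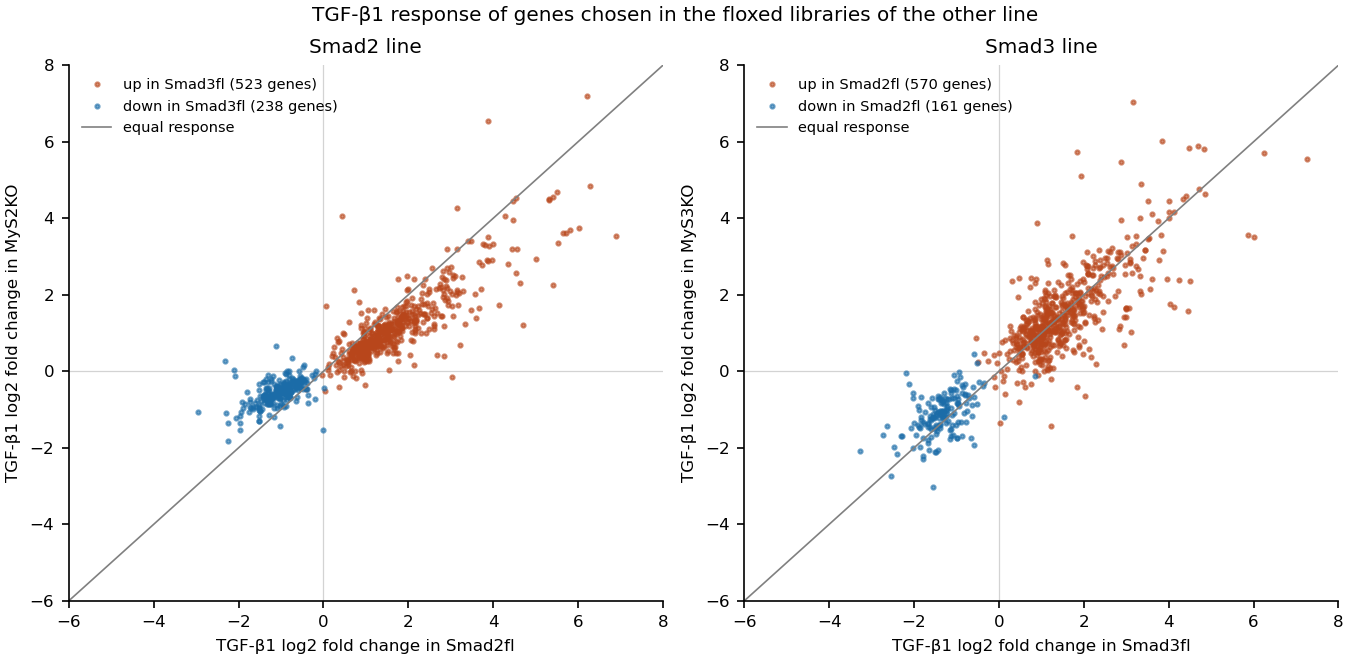
TGF-β1 log2 change in floxed (x) and knockout libraries (y) of each line, for genes chosen in the floxed libraries of the other line, with the line of equal response. Points of the Smad2 line lie nearer 0 in MyS2KO than in Smad2fl, while in the Smad3 line raised genes scatter around the diagonal and lowered genes lie nearer 0 in MyS3KO for 72%.

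Between untreated MyS3KO and Smad3fl 2531 genes were called, 1194 higher and 1337 lower in MyS3KO, 532 at least doubled and 504 at least halved. Rises prevailed in other runs, with 1909 higher and 1668 lower without untreated Smad3fl library 3, 1910 and 1590 without both Smad3fl libraries numbered 3, and 1401 and 1239 without a low-count filter. Arsb (chr13:93771630-93943016), a lysosomal sulfatase, rose from 1.03 to 61.4±3.4 CPM (5.91±0.33, adjusted p = 1.03e-10), and Timd4, a receptor for dying cells, by 3.53±0.72. Hpgd (chr8:56294585-56321043), which degrades prostaglandins, went from 3 to 196 reads over the group. The oxysterol receptor Gpr183 rose by 3.24±0.38 (2.99 to 28.2±15 CPM), Rpl29 by 3.01±0.48 (15.1 to 122±86) and the calcium pump Atp2a3 by 2.86. Trim12a went from 2801 to 2 reads over the group. Within Smad3fl it was split 8-fold, with libraries numbered 3 low under both treatments, so its fall rests on the other Smad3fl libraries. The incretin receptor Gipr fell by 6.42±0.94, the histone gene Hist1h2bq by 5.69±0.46, the lectin genes Cd209g and Cd209f by 4.75±0.39 and 4.54±0.54 and the arginase Arg1 by 4.62±0.73 (55.7±50 to 2.24 CPM). Csf3, the granulocyte growth factor, dropped to no read, at least 40.9-fold lower. Transcripts of ribosomal proteins, lower in Smad3fl, were at 1.84±0.3% of reads in MyS3KO. Counts were 1572 and 1367 without untreated Smad3fl libraries 1 and 2, 1431 and 1380 without untreated MyS3KO libraries 2 and 3, and 3577 without untreated Smad3fl library 3. With only the 2 groups compared the count was 256, and another split of the same 6 libraries called 2073. Without both Smad3fl libraries of number 3, 1 or 2 they were 3500, 1459 and 1253, and without both MyS3KO libraries numbered 1 the count was 3232.

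With TGF-β1 4017 genes were called between MyS3KO and Smad3fl, 2141 higher and 1876 lower, 818 at least doubled and 932 at least halved. Which direction prevails depends on the setting, with 2172 and 2164 by DESeq2, 1986 and 1975 with RLE factors, 1974 and 2007 without a low-count filter and 1448 and 2259 by limma on FPKM. Arsb (1.19 to 57.3 CPM, 5.61±0.33), Timd4 (5.26±0.87) and Hpgd (4.66±0.74) rose again, joined by the secreted protein Clu (3.88). Fga (4.13±0.60), Ahsg (3.91±0.44), Apoa1 (3.84), Vtn (3.73) and Apob (3.59±0.48), secreted proteins made mostly by liver, were higher too. Trim12a (-8.35), Gipr (-6.88) and Il6 (-4.16±0.91) were lower. The neighbour of Trim12a, Trim5, went from 590 to 2 reads over the group, Hist1h2bq from 510 to 3 and Csf3 from 93 to 1, and the protease Mmp10 dropped to no read, at least 26.1-fold lower. Like Trim12a, Trim5 was split 8-fold within Smad3fl, with libraries numbered 3 low under both treatments. The falls of these 2 genes thus rest on the other Smad3fl libraries. Of the called genes 927 were higher and 742 lower under both treatments (179.3 and 175.9 if independent). Without treated Smad3fl library 2 the count was 2219 and without treated MyS3KO library 3 it was 2570. Without both Smad3fl libraries of number 3, 1 or 2 it was 3889, 2821 and 2385, and without both MyS3KO libraries numbered 1 it was 3503.

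Inflammatory cytokines (24 tested) had 0 higher and 9 lower in untreated MyS3KO (0 and 12 adjusted over the list alone, median -0.80, fry adjusted p = 0.0384): Il1b fell by 3.5±0.53, the neutrophil chemokine Cxcl2 by 2.47±0.37 and the inflammasome sensor Nlrp3 by 1.67±0.21. With TGF-β1 10 were lower (10 adjusted over the list alone, fry adjusted p = 0.109), with the prostaglandin synthase Ptgs2 at -2.66±0.48. Immediate early genes had 0 higher and 10 lower (1 and 12 adjusted over the list alone, median -0.84, fry adjusted p = 0.00235), with the nuclear receptor Nr4a1 at -2.13±0.29, and did not pass with TGF-β1 (0.166). Phagocytosis genes (30 tested) had 11 higher and 3 lower untreated (14 and 4 adjusted over the list alone, median 0.37, fry adjusted p = 0.00467) and 15 and 2 with TGF-β1 (17 and 3 adjusted over the list alone, median 0.57, fry adjusted p = 0.00132). Among them were the bridging protein Pros1 (1.2±0.23), the signalling adaptor Tyrobp (0.99±0.20) and the Fc receptor Fcgr3 (1.49±0.23 with TGF-β1). Lysosome genes (23 tested) had 11 and 2, then 15 and 1 (14 and 2, then 16 and 2 adjusted over the list alone, medians 0.47 and 0.58, fry adjusted p = 0.0069 and 0.00132). The protease Ctsd was at 1.51±0.24 and 1.8 and Lamp1 at 1.07±0.19 and 1.42. With an estimated correlation none of these kept its call (adjusted p = 0.425 for cytokines, 0.279 for immediate early genes, 0.358 and 0.704 for phagocytosis, 0.41 and 0.704 for lysosome).

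Glycolysis genes (23 tested) had 0 higher and 13 lower in untreated MyS3KO (13 adjusted over the list alone, median -0.42, fry adjusted p = 4.4e-05) and did not pass with TGF-β1 (0.167). The hypoxia factor Hif1a was at -1.2±0.23, its regulator Egln3 at -1.92±0.35 and Hk2 at -0.87±0.12. Oxidative stress genes (13 tested) had 7 lower (8 adjusted over the list alone, median -0.65, fry adjusted p = 0.00235) and 6 lower with TGF-β1 (median -0.52, fry adjusted p = 0.0105). The reductase gene Gsr was at -1.56±0.21 and -1.71 and Txnrd1 at -1.25±0.16. Integrins (17 tested) had 2 higher and 9 lower (2 and 10 adjusted over the list alone, median -0.57, fry adjusted p = 5.15e-05), then 3 and 6 (3 and 6 adjusted over the list alone, fry adjusted p = 0.0232). Itgal was at -0.97±0.14, Cd44 at -1.02 and, with TGF-β1, Vcam1 at -3.01. Cholesterol synthesis genes (20 tested) had 12 higher with TGF-β1 (15 adjusted over the list alone, median 0.92, fry adjusted p = 0.0232; 0.1 untreated and 0.68 for the interaction), with the synthase Hmgcs1 at 1.01±0.22. With an estimated correlation adjusted p = 0.142 for glycolysis, 0.279 and 0.704 for oxidative stress, 0.142 and 0.704 for integrins, and 0.704 for cholesterol synthesis, so none was kept.

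TGF-β feedback genes (25 tested) had 1 higher and 8 lower in untreated MyS3KO (1 and 8 adjusted over the list alone, median -0.35, fry adjusted p = 0.000631), with thrombospondin 1 (Thbs1), which activates latent TGF-β, at -2.16±0.44, Rhob at -1.36±0.26 and Cdkn2b at -1.34±0.23. With TGF-β1 they had 4 each way (5 and 4 adjusted over the list alone, median -0.24, fry adjusted p = 0.0701). ID genes had 0 higher and 2 lower untreated, Id2 (-1.31±0.24) and Id3 (-1.79±0.36) (median -1.11, fry adjusted p = 0.000631), and 2 higher with TGF-β1, Id3 (1.20±0.31) and Smad6 (0.84±0.22) (median 0.56, fry adjusted p = 0.0232). Matrix genes (15 tested) had 2 higher and 1 lower (2 and 1 adjusted over the list alone, median 0.38, fry adjusted p = 0.0304) with osteopontin (Spp1) at 1.61±0.27. Matrix proteases (19 tested) had 2 and 6 (2 and 7 adjusted over the list alone, median -0.63, fry adjusted p = 0.0134) with Adamts4 at -2.87±0.29. Growth factors (17 tested) had 1 and 5 (1 and 5 adjusted over the list alone), down by fry (adjusted p = 0.00655) and mean (-0.28) while the median was 0.22, with Pdgfb at -1.59 and Pdgfa at -1.47. SMAD pathway members had 1 and 3, then 2 and 4 (fry adjusted p = 0.00674 and 0.0272), cell cycle genes 4 and 1, then 5 and 1 (fry up, adjusted p = 0.00235 and 0.00132, Top2a 1.9 untreated). With TGF-β1 matrix proteases (1 and 7, median -0.57), lipid efflux genes (6 and 2, median 0.39; 0.237 untreated) and macrophage identity genes (5 and 0, median 0.25, with Cebpa at 1.08; 0.183 untreated) passed at fry adjusted p = 0.0232, 0.0232 and 0.0272, and antigen presentation genes (6 and 3, median 0.43) at 0.0446 (0.319 untreated). Every call of this paragraph was lost with an estimated correlation, at adjusted p = 0.279 for feedback and ID genes, 0.41 for proteases and 0.425 for matrix genes, growth factors and SMAD members untreated, and 0.704 for those with TGF-β1.

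Lists with no call in either treatment were alternative activation genes (fry adjusted p = 0.244 and 0.977), type I interferon response (0.543 and 0.489), stress and unfolded protein response (0.0554 and 0.704), and osteoclast genes (0.544 and 0.683). The same held for microglia genes (0.396 and 0.22), chemokine receptors (0.0514 and 0.71) and heat shock genes (0.963 and 0.586). Neutrophil (0.124 and 0.123), dendritic (0.069 and 0.129), stromal (0.543 and 0.219) and erythroid markers (0.449 and 0.129) did not pass. Mitochondrial transcripts were higher in untreated MyS3KO (6 of 13, median 0.50, fry adjusted p = 0.0217; adjusted p = 0.425 with an estimated correlation), and so were 3 lymphocyte genes (Lck 1.55, median 1.27, fry adjusted p = 0.000156; adjusted p = 0.41 with an estimated correlation).

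The interaction of the Smad3 line had 3 calls and 917 genes at an unadjusted p under 0.05. Id3 (chr4:136143497-136145755) rose from 6.02±3.4 to 11.2±2.5 CPM in Smad3fl and from 1.76±0.68 to 25.7±1.3 in MyS3KO (2.99±0.48, adjusted p = 0.0377). The plasma protein genes Gc (3.00±0.53, adjusted p = 0.0481) and Alb (2.19±0.39, adjusted p = 0.0481) were the others. ID genes were up as a list (1 called, 3 adjusted over the list alone, median 1.43, fry adjusted p = 0.000906) and stayed so with an estimated correlation (adjusted p = 0.00481). Glycolysis genes (median 0.39, fry adjusted p = 0.00837) and 3 lymphocyte genes (median -1.61, fry adjusted p = 0.000906) passed and were lost at adjusted p = 0.131 and 0.187 with an estimated correlation. DESeq2 called 7 genes and limma 5, while the count was 1 with RLE factors and 0 with only the groups compared. Without a low-count filter it was 161, with 16 higher and 145 lower, so the direction turned. With an offset for gene length Id3 was at 2.92±0.48, Gc at 2.93±0.53 and Alb at 2.12±0.38, little changed, but all moved just past the threshold (adjusted p = 0.0512), which left 0 calls by edgeR and 1004 genes at an unadjusted p under 0.05. The count was 0 without untreated Smad3fl library 1 or 2, treated Smad3fl library 1 or 2, untreated MyS3KO library 2, or treated MyS3KO library 2 or 3, 1 without untreated MyS3KO library 1 or 3, and 6 without untreated Smad3fl library 3. Without both MyS3KO libraries numbered 1 it was 0.

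The knockout effects of the 2 lines differed for 703 genes untreated (298 higher and 405 lower with Smad3 loss) and for 1011 with TGF-β1 (546 and 465). Neither balance was stable, at 1137 and 811 untreated without Smad3fl library 3, and at 771 and 1137 with TGF-β1 without a low-count filter. With only the groups compared the counts were 127 (31 and 96) and 2332 (1113 and 1219). The lysosomal sulfatase gene Arsb was higher with Smad3 loss (5.63±0.42 untreated and 5.4 with TGF-β1), with Fam167b (3.94 untreated) and Gpr183 (3.47 with TGF-β1). The cytokine gene Il1a (-6.05) and Arg1 (-5.06) were lower untreated and Il6 (-6.62) with TGF-β1. Cytokines (median -1.12 untreated and -0.86 with TGF-β1), oxidative stress genes (-1.14 and -0.74), cholesterol synthesis (1.1 and 1.15), phagocytosis (0.53 and 0.61) and lysosome genes (0.48 and 0.67) differed by fry. None did with an estimated correlation (adjusted p at least 0.234 untreated and 0.35 with TGF-β1). Untreated counts lay between 244 and 444 without any 1 of Smad2fl libraries 1 and 2, MyS2KO 1 and 2, Smad3fl 1 and 2 and MyS3KO 2 and 3, and were 1948 and 1377 without Smad3fl library 3 and MyS3KO library 1. With TGF-β1 they lay between 348 and 625 without any 1 of Smad2fl libraries 1 and 2, MyS2KO 1 and 2, Smad3fl 1 and 2 and MyS3KO 2 and 3.

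The interactions of the 2 lines differed for 2 genes (450 at an unadjusted p under 0.05). The interaction of Chst3 was negative in the Smad2 line (-1.89), a weaker response in MyS2KO, and 2.96±0.40 higher in the Smad3 line (adjusted p = 0.00245). That of Bhlhe40 (chr6:108660629-108666925), a repressor that shapes macrophage proliferation, was 2.76±0.47 higher in the Smad3 line (adjusted p = 0.0404). Bhlhe40 rose from 1.15 to 10.3 CPM in Smad2fl, 1.73 to 5.79 in MyS2KO, 4.98 to 14.1 in Smad3fl and 2.9 to 20.6 in MyS3KO. TGF-β feedback genes (median 0.42, 1 called, 1 adjusted over the list alone, fry adjusted p = 0.0421) and ID genes (median 1.21, 0 called, 2 adjusted over the list alone, fry adjusted p = 0.0137) differed and stayed so with an estimated correlation (adjusted p = 0.0364 and 0.00628). The call of Bhlhe40 was lost in most runs without 1 library, where the count was 1, and the count was 4 without untreated Smad3fl library 3. With the planned block for the library number within each line it was 1. Limma on FPKM called 1 gene as well, neither Chst3 nor Bhlhe40. With a block within each genotype, chosen after the values were seen, the count was 16.

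The TGF-β1 responses of Smad3fl and Smad2fl differed for 0 genes by edgeR and limma, with 464 at an unadjusted p under 0.05 and 10 by DESeq2, and for no list (lowest fry adjusted p = 0.0695). With a block for the library number within each genotype, chosen after the values were seen, 13 were called. Without untreated Smad3fl library 3 the count was 2 and without treated Smad3fl library 1 it was 1. Untreated, however, the same lines differed for 4762 genes, 2531 higher and 2231 lower in Smad3fl. Smad3 itself was higher there (3.35±0.15, adjusted p = 1.12e-12), with Ifi202b (10.35±1.57), the chemokine Cxcl1 (6.67±0.55, 3 to 305±170 CPM) and Il1a (5.64), and Tpbg went from no read to at least 97.8-fold. Rpl29 was lower (-4.28±0.51, 293 to 15.1 CPM), as were the peptidase gene Cpe (-4.48) and Lyz2 (-1.47±0.38). Glycolysis genes (15 higher, 17 adjusted over the list alone, median 0.55, fry adjusted p = 8.05e-07) and oxidative stress genes (9 higher and 1 lower, 10 and 1 adjusted over the list alone, median 1.13, fry adjusted p = 1.51e-05) were up in Smad3fl. Phagocytosis genes (6 higher and 17 lower, 6 and 17 adjusted over the list alone, fry adjusted p = 0.00314) and lysosome genes (3 and 14, 3 and 15 adjusted over the list alone, fry adjusted p = 0.00471) were down. All were lost at adjusted p = 0.187 or 0.529 with an estimated correlation. Markers and RNA quality moved with the same groups: stromal (fry adjusted p = 0.00119) and heat shock genes (0.0287) were up in Smad3fl, and lymphocyte (0.000599), erythroid (0.00867) and mitochondrial genes (0.0154) down, all lost with an estimated correlation (adjusted p at least 0.529). Counts were 3131 without untreated Smad2fl library 2 and 2744 without untreated Smad3fl library 2.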

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

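The counts of other sample splits, and the tests of linked alleles, of the floxed lines being alike, of alleles that differ between animals and of other SMAD reads, were chosen only after the results were seen.

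In the Smad2 line the TGF-β1 response differed between floxed and knockout libraries for 1 gene, Chst3 (-1.89). In the Smad3 line it differed for 3 genes, Gc (3), Id3 (2.99) and Alb (2.19). Of 100 drawn splits of the Smad2 line 10 called as many genes as the real one or more, with 1 real call and 256 in the highest other. Of 100 of the Smad3 line 21 did, with 3 real calls and 5974 in the highest other, so chance is not excluded for either count. The number of draws was raised after smaller runs had been seen, and in the smallest of them the share for the Smad2 line was under 0.05. Genotype labels were drawn anew within each treatment, so treatment was never mixed. A split that exchanges genotypes in only 1 treatment turns the interaction into the sum of both knockout effects. In the Smad3 line these had 2531 and 4017 calls. High counts of other splits can thus stem from the knockout effects, and the shares cannot test the interaction alone. With an offset for gene length neither interaction kept a call (0 by edgeR, 500 and 1004 genes at an unadjusted p under 0.05; 5 and 7 calls by DESeq2 without it), while their difference kept 2. The folds barely moved (Chst3 -1.84±0.31 from -1.89±0.27, Id3 2.92±0.48 from 2.99±0.48, Gc 2.93±0.53 from 3±0.53, Alb 2.12±0.38 from 2.19±0.39), so the lost calls are no evidence of a length effect. Without untreated MyS2KO library 3 or treated MyS2KO library 2 the Smad2 line had 0 calls by edgeR (5 by DESeq2 with all libraries), and without untreated Smad3fl library 1 the Smad3 line had 0 (7 by DESeq2).

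Genes chosen in Smad3fl had a weaker TGF-β1 response in the libraries labelled MyS2KO than in Smad2fl, with a median interaction of -0.45 for genes that rise and 0.48 for genes that fall. In the interaction of the Smad3 line the ID genes had a median of 1.43, glycolysis genes 0.39 and lymphocyte genes -1.61, and the last 2 lost their calls with an estimated correlation (adjusted p = 0.131 and 0.187). Between the interactions of the lines Chst3 (2.96) and Bhlhe40 (2.76) made up the 2 calls, with medians of 0.42 for TGF-β feedback genes and 1.21 for ID genes. For that count 5 of 100 splits did as well, the highest other at 4110, so chance is not excluded.

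The effects of Smad3 loss and of the MyS2KO genotype differed for 703 genes untreated and 1011 with TGF-β1. Of 100 drawn splits 2 did as well untreated (highest other 1567) and 4 with TGF-β1 (highest other 2822), both under the share of 0.05 set for the test. For TGF-β1 100 draws cannot tell 4 from 5, and the number of draws was changed after results were seen, so chance is not firmly excluded there. A split that exchanges genotypes in only 1 line adds the knockout effects of both lines. High counts of other splits can stem from this. Untreated, Arsb (5.63), Fam167b (3.94) and Dexi (3.83) were higher and Gvin1 (-6.18), Il1a (-6.05) and Hist1h2bq (-5.3) lower with Smad3 loss. With TGF-β1 Arsb (5.4), Hpgd (5.18) and Gpr183 (3.47) were higher and Trim12a (-8.54), Il6 (-6.62) and Gvin1 (-5.62) lower. Gvin1 and Trim12a were split 8-fold within Smad3fl, with libraries numbered 3 low under both treatments. Their differences thus rest on the other Smad3fl libraries. None of the lists that follow differed with an estimated correlation (adjusted p at least 0.234 untreated and 0.35 with TGF-β1). List medians untreated were -0.4 for TGF-β feedback genes, -0.94 for ID genes, -0.7 for matrix proteases, -1.12 for cytokines, -0.46 for alternative activation genes and -0.4 for growth factors. They were -0.21 for glycolysis, -0.04 for integrins, -0.9 for immediate early genes and -1.14 for oxidative stress genes. On the higher side were phagocytosis (0.53), cholesterol synthesis (1.1), lipid efflux (0.55), lysosome (0.48), lymphocyte genes (1.22) and mitochondrial transcripts (0.73). With TGF-β1 medians were 0.89 for ID genes, -0.86 for cytokines, 0.61 for phagocytosis, 0.37 for cell cycle, 1.15 for cholesterol synthesis and 0.55 for lipid efflux. They were 0.67 for lysosome, 0.38 for microglia genes, -0.74 for oxidative stress genes and -0.96 for stromal markers. Counts without single libraries, such as 244 without untreated MyS3KO library 3 and 1948 without untreated Smad3fl library 3, stand beside these results in the report.

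In comparisons of 3 against 3 libraries the 10 splits cannot give a share under 0.05, so these counts decide nothing about chance, and in each only 1 split, the real one, reached the real count. For TGF-β1 the real counts and highest others were 1584 and 0 in Smad2fl, 486 and 1 in the libraries labelled MyS2KO, 1714 and 18 in Smad3fl and 1428 and 1 in MyS3KO. The labels give no pairs. If libraries of equal number are taken as pairs, the other splits that part all 3 pairs called 0 in every genotype. Those that keep a pair together on each side called at most 0 in Smad2fl, 1 in MyS2KO, 18 in Smad3fl and 1 in MyS3KO. For the knockout comparisons they were 10 and 0, and 60 and 0, in the Smad2 line, and 2531 and 2073, and 4017 and 0, in the Smad3 line. For the untreated floxed lines they were 4762 and 1552. For the difference of floxed responses, 0 by edgeR (464 at an unadjusted p under 0.05, 10 by DESeq2), all 100 drawn splits reached the real count, as they must with a count of 0, so they say nothing about chance (highest 6888).

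Most Smad3fl libraries stand apart from all other groups, while untreated number 3 scored 6.9 on the first component, close to MyS3KO. Gene length bias is argued against, since 3923 genes were called for Smad3 loss with TGF-β1 after an offset for length against 4017 before. That the floxed lines are otherwise equal is argued against by 4762 genes called between them untreated and by Ifi202b, at 80.7 to 275 CPM in Smad3fl and at most 0.46 in the Smad2 line, while the 2596 genes called opposite ways for untreated Smad3fl over Smad2fl and treated MyS3KO over Smad3fl (667.8 if independent) decide less, as Smad3fl libraries of equal number resemble each other. Alleles that differ between animals are 1 candidate explanation for the spread within the line: of 21 genes split 8-fold within a genotype 19 (90.5%, chance 16.7%) set the same library number apart in both treatments, but so did 2 of 2 in Smad2fl and 5 of 5 in MyS2KO, and whether numbers are animals is not given. Whether linked strain alleles act in blocks cannot be told apart from other causes. Called genes had a called neighbour 1.86 times as often as with shuffled positions, between the bounds set for the test. The lowered Smad3 itself stays open as part of the difference.

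Plasma protein genes such as Alb were higher in treated knockout libraries of both lines, at 16.5 CPM in Smad2fl and 39.4 in MyS2KO, and 12.1 in Smad3fl and 78.3 in MyS3KO. Trace liver RNA is a candidate source: of liver markers not looked at before, 22 of 23 detected (95.7%) were higher in both treated knockout groups. Of markers listed for other organs 2 of 11 were, Mbp and Fabp1, and Fabp1 is made in liver as well. Mbp lay at 34.3 and 34.5 CPM in treated Smad2fl and MyS2KO, and Mylpf and Cela1 at 3.19 CPM or more in every group. Such genes say little about RNA of other organs. Without TGF-β1 16 of those 23 liver markers were higher in both knockout groups too. Of markers listed for other organs and not looked at before 2 of 10 were. Of all 35 liver markers 2, Alb and Apoa2, reached 1 CPM in untreated Smad2fl, and together they made up 34.5 CPM in treated Smad2fl, 84.4 in MyS2KO, 25.6 in Smad3fl and 164 in MyS3KO. The increases kept similar proportions in both lines (SD of the log2 ratio 0.67), which may point to 1 source. A change of these genes in the macrophages themselves was not tested apart from this. The muscle transcripts Myh4, Acta1, Tnnt3 and Ckm reached 3.39, 3.29, 2.3 and 1.23 CPM in treated MyS2KO, and at most 0.459 in treated MyS3KO. Mylpf and Myh6 did not rise (6.49 and 0.249 CPM in treated Smad2fl, 6.43 and 0 in MyS2KO). A rise in only 1 line does not enter the share of 2 of 11.

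Smad3 lay at 161 CPM or more in MyS3KO, above the 66.6 CPM that the Smad2 line reached at most, and was higher still in Smad3fl. A gain of the surrounding region is argued against by a median difference of 0.16 for 18 tested genes within 1 Mb, between -1.31 and 2.34. Whether reads of another SMAD gene were counted as Smad3 is not decided. The largest fall of another SMAD gene came to 1.3% of the gain of Smad3. No other SMAD gene exceeded 47.7 CPM in untreated Smad2fl, against a gain of 382 CPM, so no possible fall could have matched it. A duplication of Smad3 alone, a difference in its promoter or the targeted allele itself stays open, untested.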

How the results depend on the processing

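The block for library number within each genotype and the runs without both libraries of a number were chosen only after the results were seen. None of the named genes called with all libraries changed sign under the alternatives run for it, other called genes were not followed, and medians of some called lists did change sign. Where values moved the cause was not tested unless named. Among results without a call, Lyz2 in untreated MyS3KO went from -0.48 to 0.14 without both Smad3fl libraries numbered 3, and with TGF-β1 from -0.06 to 0.24. Smad2 in treated MyS2KO went from 0.09 to -0.04 without treated MyS2KO library 2, and the list of genes up in Smad2fl ranged from -0.16 to 0.06 in the Smad3 interaction (0.01).

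Libraries of equal number resembled each other most clearly in Smad3fl. In Smad2fl each was closest to its own number as well, but weakly (r = 0.05, 0.13 and 0.16, highest other 0.04). In MyS2KO not all were (0.15, 0.22 and 0.41, highest other 0.2). With a block for the number within each genotype TGF-β1 called 3237 genes in Smad2fl, 1032 in MyS2KO, 3306 in Smad3fl and 2749 in MyS3KO, with 2 and 6 calls in the interactions of the Smad2 and Smad3 lines, 16 in their difference and 13 in that of the floxed responses. With a block within each line the Smad2 line had 19 calls untreated and 0 in its interaction, and the difference of interactions 1.

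With RLE factors the Smad3 interaction had 1 call. Without a low-count filter the Smad2 line had 161 calls untreated and 313 with TGF-β1, Lyz2 -0.91 (adjusted p = 0.000245) and -0.96 (adjusted p = 4.8e-05), and interactions 13 and 161, the latter with 16 higher and 145 lower. The knockout effects of the lines then differed for 1240 and 1908 genes, interactions for 12 and floxed responses for 22. DESeq2 gave 101 and 214 in the Smad2 line, 5 and 7 in the interactions, 1213 and 1668 between knockout effects, 11 between interactions and 10 between floxed responses. Limma on FPKM gave 0 and 5 in the interactions and 1 in their difference. Camera with a preset correlation passed genes down in Smad2fl in the Smad3 interaction (0.26, adjusted p = 0.000685), as did no fold minimum (0.25, adjusted p = 0.0431).

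With only the groups compared, and so fewer samples, TGF-β1 called 1004 genes in Smad3fl and 893 in MyS3KO. The Smad2 line had 0 untreated by edgeR (1254 at an unadjusted p under 0.05 with all groups) and 271 with TGF-β1, with Lyz2 at -0.96 (adjusted p = 0.00638). Smad3 loss untreated had 256, both interactions 0, the knockout effects differed for 127 and 2332, and the floxed lines for 2209.

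Without both Smad3fl libraries numbered 3 TGF-β1 called 978 genes in Smad3fl, untreated knockout effects differed for 1913 and floxed responses for 1. Without those numbered 1 these were 1130, 346 and 2, with 1459 for Smad3 loss untreated, 0 for its interaction and 1 for the difference of interactions. Without those numbered 2 Smad3fl had 1138, Smad3 loss 1253 and 2385, its interaction 0, knockout effects 212 and 466, interactions 1 and floxed lines 2531. Without both MyS3KO libraries numbered 1 Lyz2 in untreated MyS3KO was -0.9 (adjusted p = 0.0416), the Smad3 interaction had 0, knockout effects differed for 1621 and 1544 and interactions for 1.

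Without single libraries TGF-β1 called 1057 to 1569 genes in Smad2fl, 316 to 451 in MyS2KO, 1136 to 1993 in Smad3fl and 914 to 1557 in MyS3KO. The Smad2 line had 2 to 12 and 0 to 57, the Smad3 line 1367 to 3577 and 2219 to 3318, interactions 0 to 1 and 0 to 6. Knockout effects differed for 244 to 1948 and 348 to 1377 genes, interactions for 1 to 4, floxed responses for 0 to 2 and floxed lines for 2744 to 5970. The list of genes down in Smad3fl lay between 0.4 and 0.57 in the Smad2 interaction, and that of genes up between -0.51 and -0.4. Smad3 in MyS3KO stayed between -1.3 and -1.11 untreated and between -0.68 and -0.59 with TGF-β1, and called throughout.

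Of 84 results of gene lists 24 kept direction and side of the threshold under every alternative, and of 1199 results of named genes 607 did. For lists 274 of 1246 values and for genes 3167 of 18861 were weaker and no longer past the threshold.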

Other observations

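The test of genes raised in both floxed lines was chosen before its result was seen.

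A hypothesis was that the TGF-β1 response is weakened more in the Smad2 line than in the Smad3 line. The 695 genes called higher in both floxed lines had a median interaction of -0.38 in the Smad2 line and -0.05 in the Smad3 line, with a median difference of 0.31 (fry with 0.00141 unadjusted). These genes were chosen on floxed libraries that both interactions subtract, a choice that tends to lower both medians, so the test leaves the hypothesis open. Lists chosen in the other line are free of this, with -0.45 in the Smad2 line and 0.01 in the Smad3 line for raised genes and 0.48 and 0.26 for lowered genes, which were not tested against each other. The 404 genes called lower in both did not differ in the same test (0.38 and 0.28, difference -0.11, fry with 0.294 unadjusted).

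Some genes differed in level between libraries of a genotype. Rpl29, a ribosomal protein gene, was at 221 and 238 CPM in MyS3KO libraries numbered 1, at 57.1 to 75.6 in those numbered 2 and 3, at 8.06 to 24.8 in Smad3fl and at 221 to 317 in the Smad2 line.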
